A study of Mus musculus with 10 samples.

How the data were processed

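RNA from the cochleae of female mice was measured on 10 one-colour Affymetrix arrays. Per the labels, each array carried biotin-labelled cRNA from a pool of 8 mice aged 10 weeks, and the arrays of a group are biological replicates. The strains were 129X1/SvJ, an inbred strain, and B6.CAST, a C57BL/6J background strain that carries a segment from CAST mice around Cdh23. Noise-exposed mice received an octave band of noise at 10 kHz and 105 dB SPL for 1 h and were killed 6 h later, and control mice were placed in the chamber without noise. There were 3 control and 3 noise arrays of 129X1/SvJ and 2 control and 2 noise arrays of B6.CAST. Per the labels, the strain name of the last control and the last noise array of 129X1/SvJ is spelled differently, and both were kept in that strain.

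The deposited values are linear signal intensities per probe set, with 1 decimal. The values show that the authors' table had been scaled array by array, since the mean after dropping the lowest and highest 2% of probe sets is about 500 on every array (lowest 499.862, highest 499.874). The software, its version and the scaling target are not given in the sources used here, and no detection flags were used here. The table holds 12488 probe sets, of which 66 are control probe sets, and all of its columns belong to the 10 samples. Of the probe sets, 10855 have 1 gene symbol in the platform annotation, 396 have several genes and 1237 are unnamed here. Symbols were updated through gene identifiers with the RefSeq table of GRCm38.p6, in which 10839 of the probe sets with 1 gene were found. The deposited values name no genome build, so no coordinates are printed.

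From these values, log2(intensity + 16) was computed and the arrays were quantile normalized. Fold changes are on this log2 scale, which understates the change of dim genes. Control probe sets and the 30% of other probe sets with the lowest mean were left out, which left 8695 probe sets with a mean corresponding to a signal above 42.9. In limma 3.58.1 (R 4.3.3), 4 group means were fitted to all 10 arrays, contrasts were moderated with a variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Errors of log2 changes are standard errors from that fit. The p-values measure the spread between arrays, that is, between pools of mice. The number of arrays limits the precision.

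There were 6 comparisons: noise against control in each strain, the mean of the 2 noise effects, their difference (B6.CAST minus 129X1/SvJ), and B6.CAST minus 129X1/SvJ in control and in noise-exposed mice. The brightest probe set stood for each of 6506 genes in gene lists and in the choice of named genes. Named genes follow a rule set before the data were examined: up to 12 of the largest rises and up to 12 of the largest falls past the threshold. Where fewer than 10 genes passed, the rule also took 6 per direction with the smallest p among genes whose groups did not overlap. It further took up to 4 members of each gene list with the smallest p, and Nnt and Cdh23 as checks of the strain labels. Genes named outside this rule are marked as chosen after their values were seen.

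The 22 gene lists and marker lists, set together with that rule, were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation. Beside it fry, also from limma, tested whether the genes of a list moved on balance in 1 direction, without comparing them with other genes. They covered immediate early, heat shock, cytokine, antioxidant, apoptosis, glucocorticoid-responsive, circadian and interferon-induced genes, genes near Cdh23, and markers of hair cells, supporting cells, stria vascularis, spiral ligament, spiral ganglion neurons, Schwann cells, bone, erythroid cells, neutrophils, macrophages, lymphocytes, skeletal muscle and endothelium. Of 460 list entries, 356 were on the array.

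The fits were tested on simulated data with the means and spreads of the 8695 probe sets and 200 changed ones. Values were drawn independently for each probe set, with the same spread on every array. Correlated genes and arrays that stand apart were not simulated, so real recovery may differ. For noise in 129X1/SvJ, 41 of 100 changes of 1 on the log2 scale and 87 of 100 changes of 2 were recovered, with 7 false calls among 135. For noise in B6.CAST, 33 and 80 of 100 were recovered, and for the difference of noise effects 15 and 65 of 100. Alternatives covered the scaling, the pseudocount, the filter, the variance trend, array weights, the arrays in the fit, each array left out, the replicate number as a block, the threshold and the gene list test.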

Results

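The data are signal intensities of cochlear RNA from 2 mouse strains that differ in their susceptibility to noise damage, with and without exposure to noise. Of 129X1/SvJ there were 3 control and 3 noise arrays, and of B6.CAST 2 control and 2 noise arrays. Correlations of log2 values ranged from 0.925 to 0.969 between arrays of the same group and from 0.894 to 0.976 between arrays of different groups. The first noise array of 129X1/SvJ stood apart, with a mean correlation of 0.910 with the other arrays, against 0.943 to 0.955 for the rest. The ratio of the 3′ to the 5′ control probe set of Gapdh, a sign of RNA quality, was 29.2 on the second control array of 129X1/SvJ and 6.94 on the first noise array of B6.CAST, and between 0.790 and 1.40 on the others.

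In 129X1/SvJ, noise raised transcription factors and other genes of the immediate early response together with chemokines. Fos, a subunit of the AP-1 transcription factor, rose by 4.95 ± 0.38 on the log2 scale (SE, n = 3 noise and 3 control arrays), from a mean signal of 99.6 to 4206. Ccl2 and Ccl7, which attract monocytes, rose by 4.08 ± 0.41 and 3.50 ± 0.53, and Cxcl1, which attracts neutrophils, rose by 2.93 ± 0.41. Gem, a small GTPase, rose by 3.56 ± 0.31. The 4 falls were smaller and included Kl, the co-receptor klotho, at -1.23 ± 0.20, and Aass, an enzyme of lysine breakdown, at -1.04 ± 0.16.

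All 24 tested immediate early and AP-1 genes were higher with noise, of which 22 passed when adjusted over the list alone and 8 passed over all probe sets. Besides Fos these included the nuclear receptor Nr4a1 (2.84 ± 0.32), the stress gene Gadd45b (3.14 ± 0.23), Ier3 (1.87 ± 0.16) and the transcription factors Egr1 (2.20 ± 0.41) and Atf3 (2.15 ± 0.34). Of the 23 tested cytokine, chemokine and acute inflammation genes, 20 were higher with noise. Over all probe sets 6 passed as higher and none as lower, and 18 passed when adjusted over the list alone. This list includes Socs3, an inhibitor of cytokine signalling, at 2.07 ± 0.32, and the transcription factor Cebpd at 1.55 ± 0.20. Both lists passed camera at its preset correlation (adjusted p = 2.3e-34 and 8.6e-21). Each had adjusted p = 0.065 with an estimated correlation, so neither camera call held. Both passed fry (adjusted p = 0.0096 and 0.0099), the only 2 of the 22 lists that did. Other rises were the growth factor Hbegf (2.03 ± 0.26), the casein gene Csn3 (2.76 ± 0.27) and the inducible heat shock gene Hspa1a (1.42 ± 0.15). The homeobox gene Msx3 fell by 1.34 and Nde1 by 0.72. When each of the 10 arrays was left out in turn, Msx3 passed in every fit and Nde1 in none (lost in 10 of 10). Dusp1 was lost in 7 of these fits, Egr1 in 6, Kl and Aass in 4 each, Atf3 and Socs3 in 3 each and Ccl7 in 2.

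At the preset correlation, 5 further lists were higher with noise in 129X1/SvJ: glucocorticoid-responsive genes, heat shock genes, and markers of macrophages, of neutrophils and of spiral ganglion neurons. None held, with adjusted p = 0.54 with an estimated correlation for neutrophil markers and 0.40 for the other lists. Of these lists, 2 of 18 glucocorticoid-responsive genes (Cebpd and Dusp1) and 1 of 20 heat shock genes passed as higher over all probe sets. When adjusted over the list alone, 5 and 3 passed. Cebpd is also on the cytokine list and Dusp1 on the immediate early list, so these calls are not separate from those above. Among neutrophil markers 0 of 13 passed in limma and 1 had an unadjusted p under 0.05, and the median was 0.76. Their mean deviation from the average of all arrays was 1.80 on the first noise array, against 0.13 and 0.58 on the other noise arrays. The mean change of these markers was 0.83, and 0.23 without the first control array, where the call was lost, as it was without the first noise array. The mean of glucocorticoid-responsive genes went from 0.55 to 0.23 without the first noise array, that of macrophage markers from 0.30 to 0.14 without control 1, and that of heat shock genes from 0.20 to 0.13 without control 3, with the call of both latter lists lost. The call of spiral ganglion neuron markers was lost in 4 of 10 such fits.

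In all, limma called 44 of 8695 probe sets in 129X1/SvJ, 40 higher and 4 lower with noise. The count was 24, 22 and 27 without the control arrays 1, 2 and 3 in turn, and 30 without the first noise array. Gadd45b, Atf3 and Socs3 were measured with probe sets that may match related sequences, and their second probe sets gave 2.19, 1.07 and 3.23, of which that of Atf3 did not pass (adjusted p = 0.28).

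**Figure D1:**
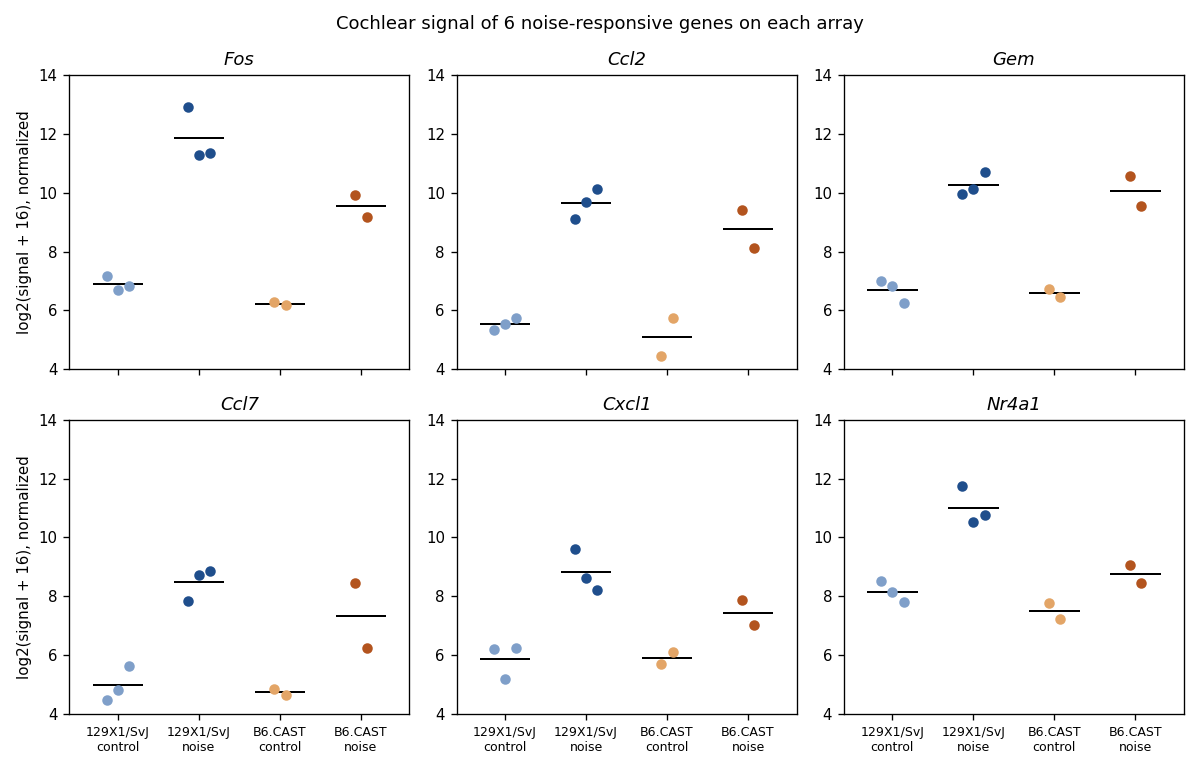
Normalized log2(signal + 16) of 6 genes on each array, with the 4 groups along the horizontal axis, points for arrays and lines for group means. All noise arrays lie above all control arrays of their strain, and Fos reaches 12.91 on the first noise array of 129X1/SvJ.

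In B6.CAST, the same 3 leading genes passed. Ccl2 rose by 3.66 ± 0.51 (SE, n = 2 noise and 2 control arrays), Gem by 3.46 ± 0.38 and Fos by 3.33 ± 0.47. The mean signal of Fos was 57.5 in control and 768 in noise-exposed mice. Genes that did not pass but whose groups did not overlap included Ier3 (1.21 ± 0.20), Dio2, which activates thyroid hormone (1.28 ± 0.21), Dusp1 (0.89 ± 0.17) and Cebpd (1.25 ± 0.24). In the other direction they included Ndp, a Wnt pathway ligand, at -0.996 ± 0.21, and the neutrophil genes Mpo and S100a9, at -2.69 ± 0.86 and -2.49 ± 0.81. Without the first control array of B6.CAST these were -1.73 and -1.46. With 2 arrays in each group, 2571 of the 8695 probe sets (29.6%) did not overlap, so this trait alone sets no gene apart. When each array was left out in turn, the calls of Fos and Ccl2 were each lost in 8 of 10 fits and that of Gem in 3.

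All 24 tested immediate early genes were higher with noise in B6.CAST, as in 129X1/SvJ. Of these, 1 passed over all probe sets and 7 passed when adjusted over the list alone. With 2 arrays in each group against 3, these counts of passing genes are not directly comparable with those of 129X1/SvJ. Of the 23 cytokine and chemokine genes, 22 were higher, 1 passed over all probe sets and 8 passed when adjusted over the list alone. Both lists passed camera at the preset correlation, with median changes of 0.54 and 0.62, and gave an adjusted p = 0.23 and an adjusted p = 0.17 with an estimated correlation. Interferon-induced and glucocorticoid-responsive genes were also higher as lists, with medians of 0.44 and 0.38. Markers of neutrophils (median -1.92), erythroid cells (-0.83), lymphocytes (-0.32) and bone (-0.28) were lower. With an estimated correlation none of these held: adjusted p = 0.27 for neutrophils, 0.48 for bone and 0.37 for the others. Of the 13 neutrophil markers, 0 passed in limma over all probe sets, 7 had an unadjusted p under 0.05, and 4 passed as lower when adjusted over the list alone. In fry, 0 of the 22 lists passed. Without the first noise array of B6.CAST, 5 lists passed camera in place of 8. That array had the Gapdh ratio of 6.94 and a mean deviation of interferon-induced genes of 0.82, against 0.31 on the other noise array. Without it, the mean of interferon-induced genes went from 0.35 to 0.087 and that of lymphocyte markers from -0.37 to -0.11, both with the call lost, and that of cytokine and chemokine genes from 0.84 to 0.56. Without the first control array, on which neutrophil markers lay at 1.16 against -0.65 on the other, the mean of neutrophil markers went from -1.77 to -0.93, that of erythroid markers from -0.76 to -0.092 and that of bone markers from -0.47 to 0.017. The calls of erythroid, bone and lymphocyte markers were then lost.

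The test called 4 of 8695 probe sets in B6.CAST, all higher, among them 1 probe set without a gene name here. An unadjusted p under 0.05 was found for 183 probe sets, against 434.75 from chance alone. The count was 0 without B6.CAST control 1 or noise 1, 1 without its control 2 and 2 without its noise 2. It was 2, 1 and 1 without the 129X1/SvJ control arrays 1, 2 and 3, and 2 and 1 without the noise arrays 1 and 2 of that strain. With the B6.CAST arrays alone it was 0.

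Averaged over both strains, Fos rose by 4.14 ± 0.30 (SE, n = 5 noise and 5 control arrays), Ccl2 by 3.87 ± 0.33, Gem by 3.51 ± 0.24 and Ccl7 by 3.04 ± 0.42. Bcl3, a regulator of NF-kappaB, rose by 2.22 ± 0.34, and the macrophage gene Cd14 by 0.86 ± 0.16. Kl (-0.98 ± 0.16), Msx3 (-0.80 ± 0.12), Ndp (-0.78 ± 0.14) and Tmem37 (-0.49 ± 0.09) fell. The fall of Msx3 came mostly from 129X1/SvJ. In B6.CAST its log2 values were 9.57 and 9.78 on control arrays and 9.26 and 9.57 on noise arrays. Immediate early genes and cytokine and chemokine genes were the 2 lists that held with an estimated correlation, each with adjusted p = 0.049 in camera. Of the immediate early genes, 24 of 24 were higher, 7 passed over all probe sets and 21 when adjusted over the list alone. For cytokine and chemokine genes these counts were 21 of 23, 8 and 18. Glucocorticoid-responsive and interferon-induced genes and macrophage markers passed at the preset correlation only, with adjusted p = 0.33, 0.42 and 0.52 with an estimated correlation. Without the first control array of 129X1/SvJ, 8 lists passed in place of 5. In fry, 3 of the 22 lists passed, which were immediate early genes, cytokine and chemokine genes, and antioxidant and metallothionein genes (adjusted p = 0.030). Tmem37 was measured with a probe set that may match related sequences. When each array was left out in turn, the calls of Tmem37, Ndp, Kl and Msx3 were lost in 10, 8, 6 and 4 of 10 fits, that of Cd14 in 8, that of Bcl3 in 3 and that of macrophage markers in 6, while Fos, Ccl2 and Gem passed in each. The mean of interferon-induced genes went from 0.25 to 0.12 without the first noise array of B6.CAST, and that of glucocorticoid-responsive genes from 0.43 to 0.27 without that of 129X1/SvJ. The count was 40 probe sets, 36 higher and 4 lower. It was 18, 26 and 18 without B6.CAST control 1, control 2 and noise 1 in turn, and 10 without both arrays of high Gapdh ratio, an alternative chosen after seeing the data.

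**Figure D2:**
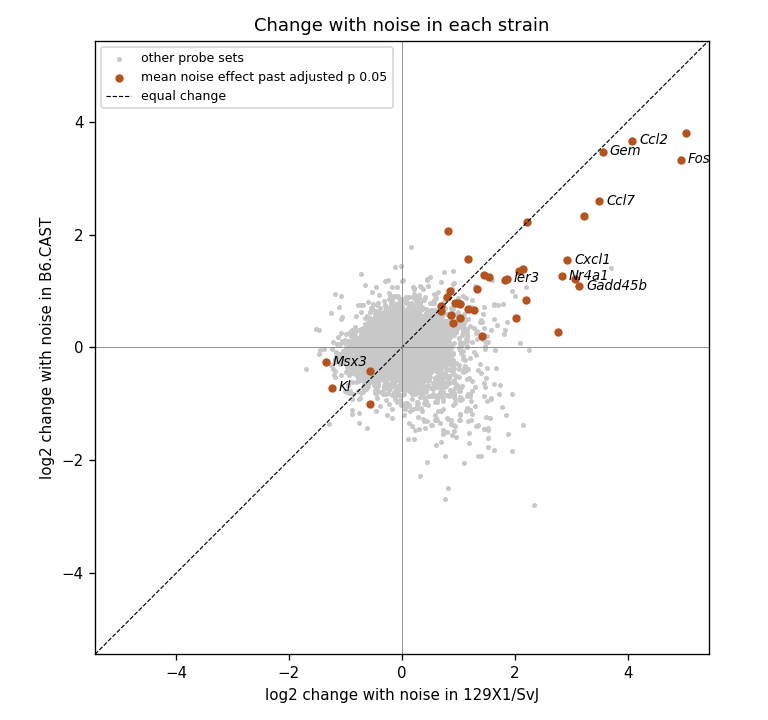
Log2 change with noise of each of 8695 probe sets in 129X1/SvJ (horizontal) and B6.CAST (vertical), with the 40 probe sets called for the mean effect in brown. Of the 36 called rises, 30 lie below the dashed line of equal change.

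The difference between the noise effects asks whether the strains responded differently. No probe set passed in limma (0 of 8695), while 258 had an unadjusted p under 0.05, against 434.75 from chance. Here too the pooled spread may be too wide, so the shortfall does not show equal responses. The 36 probe sets that rose in the mean effect had a median change of 1.68 in 129X1/SvJ and 1.13 in B6.CAST, and genes are not independent replicates. As a list, immediate early genes had a median difference of -0.84 (B6.CAST minus 129X1/SvJ), with 22 of 24 members lower. The list passed camera at the preset correlation (adjusted p = 5.5e-14) and had adjusted p = 0.40 with an estimated correlation. Gadd45b (-2.06 ± 0.36) passed when adjusted over the list alone. Nr4a1 (-1.58 ± 0.51) and Fos (-1.62 ± 0.60) did not. The mean difference of immediate early genes was -0.78, against -0.48 without the first noise array of 129X1/SvJ.

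Neutrophil markers differed in the same direction, with a median difference of -2.48 and 9 of 13 members past the threshold when adjusted over the list alone (adjusted p = 0.40 with an estimated correlation). Cytokine, heat shock, macrophage, lymphocyte, erythroid, bone and spiral ganglion neuron lists also had negative differences at the preset correlation, and none held, with adjusted p = 0.60 for bone and 0.44 for the others with an estimated correlation. In fry, 0 of the 22 lists passed. Without the first noise array of 129X1/SvJ, 4 lists passed camera in place of 9. Among genes of small p that did not pass were C1ra, a complement protease (1.24 ± 0.27), whose other probe set gave 0.32, and Hivep3 (-1.86 ± 0.56).

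**Figure D3:**
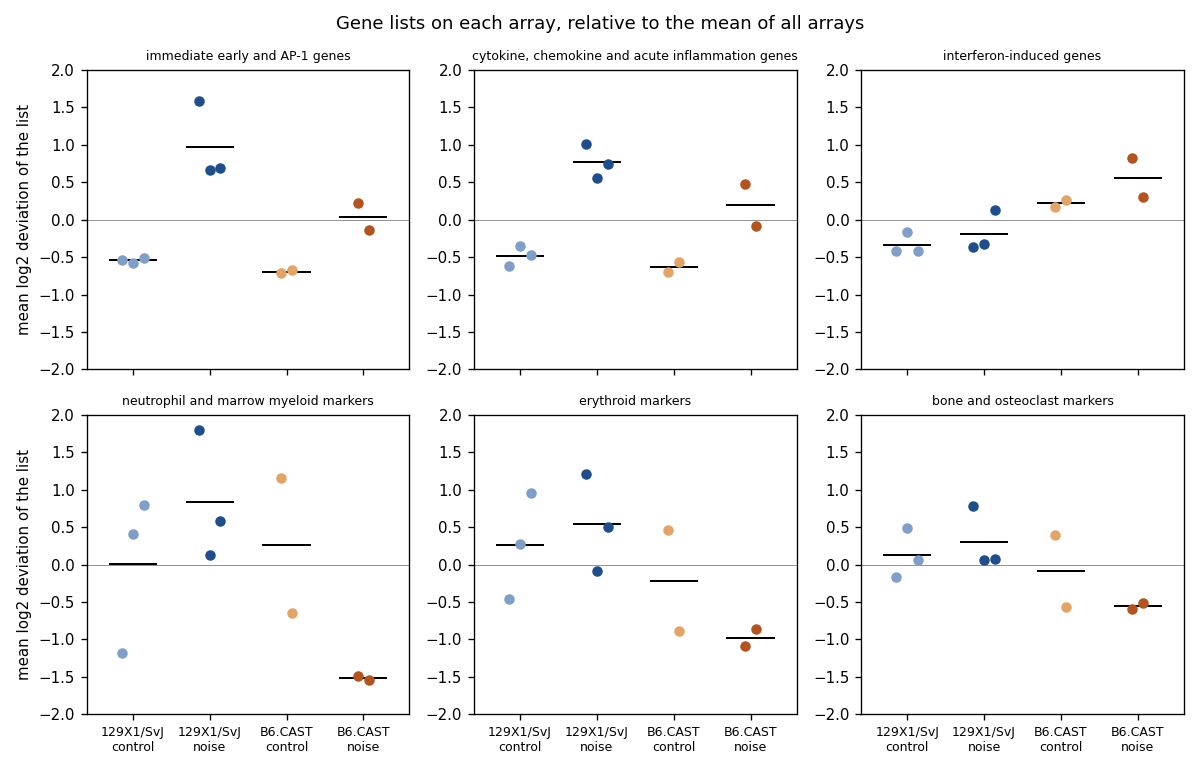
Mean log2 deviation of the members of 6 gene lists on each array from the mean of all arrays, with groups along the horizontal axis, points for arrays and lines for group means. Neutrophil markers range from -1.18 to 1.16 over control arrays and lie at -1.49 and -1.54 on the noise arrays of B6.CAST.

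In control mice, B6.CAST differed from 129X1/SvJ in 80 probe sets, 50 higher and 30 lower in B6.CAST. Higher genes included the RNA genes Gas5 (2.60 ± 0.25; SE, n = 2 and 3 arrays) and Snhg6 (2.38 ± 0.22), the securin gene Pttg1 (2.38 ± 0.18), the tight junction gene Cldn8 (2.92 ± 0.57) and the pericyte gene Rgs5 (1.74 ± 0.28). Lower genes included Fbp1, an enzyme of gluconeogenesis (-3.88 ± 0.33), Pam, which amidates peptides (-3.07 ± 0.30), the growth factor binding gene Igfbp3 (-2.45 ± 0.33), Fxyd2, a regulator of the sodium pump (-2.33 ± 0.15), and the Wnt inhibitor Sfrp1 (-2.30 ± 0.37). Nnt, which is deleted in part in C57BL/6J mice, was at -0.81 ± 0.24 and did not pass (adjusted p = 0.215 in limma). Whether its probes lie in the deleted part was not examined. Cdh23 was not analysed here.

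Among lists, interferon-induced genes were higher in control B6.CAST (median 0.53, 2 of 17 called and 5 when adjusted over the list alone), with Rsad2 at 1.69 ± 0.32 and Isg15 at 0.96 ± 0.18. Macrophage markers were higher (median 0.29), with Ctss, a lysosomal protease, at 1.01 ± 0.20 as 1 call of 11 and 3 when adjusted over the list alone. When each array was left out in turn, the calls of Isg15 and Ctss were each lost in 8 of 10 fits and that of Rsad2 in 5. The call of stria vascularis markers was lost in 6, and those of heat shock genes, glucocorticoid-responsive genes and Schwann cell markers in 2 each. Heat shock genes and stria vascularis markers were higher, and glucocorticoid-responsive genes and Schwann cell markers lower, with no member called. With an estimated correlation none of the 6 lists held, with adjusted p = 0.74 for glucocorticoid-responsive genes and 0.54 for the others. In fry, 0 of the 22 lists passed. Of the 23 tested genes near Cdh23, 0 passed in limma and 3 had an unadjusted p under 0.05.

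For 22 called probe sets, the gene had another tested probe set, whose change was a median of 0.148 of the called one. For Arcn1 (3.30 ± 0.66) the other probe set gave 0.45, for Pla2g12a (2.76 ± 0.23) 0.40, and for Igfbp3 0.41, in the opposite direction. The other probe sets of Gas5 (1.28) and Rgs5 (2.78) did not pass, and those named for Arcn1, Pla2g12a, Gas5 and Pttg1 may match related sequences. When each array was left out in turn, the call of Arcn1 was lost in 8 of 10 fits, that of Cldn8 in 7, those of Rgs5 and Sfrp1 in 3 each and that of Igfbp3 in 2. The count of 80 was 33 and 39 without the control arrays 2 and 3 of 129X1/SvJ, 132 and 53 without its noise arrays 1 and 2, and 23 and 28 without the control arrays 1 and 2 of B6.CAST.

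In noise-exposed mice, 126 probe sets differed between strains, 76 higher and 50 lower in B6.CAST. Gas5 (2.80 ± 0.25), Snhg6 (2.70 ± 0.22) and Pttg1 (2.44 ± 0.18) were higher, and Plbd1 (-3.01 ± 0.19), Fbp1 (-2.84 ± 0.33) and Pam (-2.70 ± 0.30) lower (SE, n = 2 and 3 arrays). Of the genes that rose with noise in 129X1/SvJ, Fos (-2.29 ± 0.43), Gadd45b (-2.34 ± 0.25), Nr4a1 (-2.24 ± 0.36) and Hspa1a (-1.10 ± 0.17) were lower in B6.CAST, while Gem (-0.20 ± 0.34), Ier3 (-0.38 ± 0.18) and Ccl2 (-0.87 ± 0.46), named here after their values were seen, did not pass. Also lower were Chil3, a gene of myeloid cells (-3.24 ± 0.60), the haemoglobin gene Hbb-b2 (-2.51 ± 0.53) and the muscle gene Myl1 (-1.98 ± 0.35). Under the alternatives run, the difference was as small as -1.20 for Chil3 and -0.87 for Hbb-b2. The melanin gene Dct, a marker of stria vascularis, was higher (0.78 ± 0.13). When each array was left out in turn, the call of Hbb-b2 was lost in 8 of 10 fits, those of Fos, Dct, Chil3 and Myl1 in 2, 2, 3 and 3, and those of Nr4a1 and Hspa1a in 1 each.

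Immediate early genes were lower as a list (3 of 24 called, 13 when adjusted over the list alone), as were neutrophil markers (1 of 13, and 11) and erythroid markers (1 of 9, and 6). Interferon-induced genes were higher (3 of 17, and 9), with Gbp2 at 1.70 ± 0.37 and Ifi27 at 0.72 ± 0.12. Without the first noise array of B6.CAST the mean of this list went from 0.75 to 0.49, and Gbp2 to 1.10, and the call of Gbp2 was lost in 8 of 10 fits that each left out an array, and that of Ifi27 in 2. Each of these 4 lists had adjusted p = 0.29 with an estimated correlation. Cytokine, spiral ganglion neuron, bone and glucocorticoid-responsive lists were lower and stria vascularis markers higher at the preset correlation. They had adjusted p = 0.31 for bone and glucocorticoid-responsive genes and 0.30 for the other lists with an estimated correlation. Without the second noise array of B6.CAST the mean of stria vascularis markers went from 0.22 to -0.094 and that of cytokine and chemokine genes from -0.57 to -0.29. Without the first noise array of 129X1/SvJ that of glucocorticoid-responsive genes went from -0.60 to -0.28, and the calls of this list and of bone markers were lost. In fry, 0 of the 22 lists passed. The count was 80 without the second noise array of 129X1/SvJ, and 35 and 26 without the noise arrays 1 and 2 of B6.CAST. With the mean of neutrophil and erythroid markers as a covariate, an alternative chosen after seeing the data, it was 17. The covariate itself separated these arrays, at 1.56, 0.042 and 0.55 for 129X1/SvJ and -1.33 and -1.26 for B6.CAST. Such a split alone widens the errors, so the lower count does not show that marrow explains the strain differences.

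The strain differences of control and of noise-exposed mice compare separate arrays, but the fit shares a single estimate of spread for each probe set. The lists are therefore not independent, and the values for independent lists below are only a reference. A sequence variant under the probes would also recur in both comparisons. Of 50 probe sets higher in control B6.CAST, 32 were also called higher after noise, against 0.437 for independent lists. Of the 30 lower ones, 22 were also called lower, against 0.173.

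**Figure D4:**
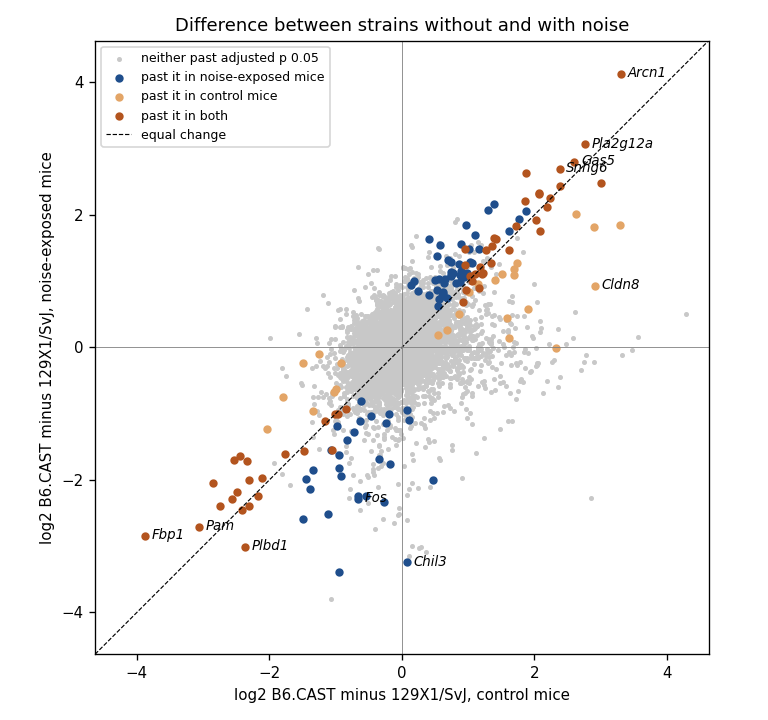
Log2 difference between strains (B6.CAST minus 129X1/SvJ) of each probe set in control mice (horizontal) and in noise-exposed mice (vertical), coloured by the comparison in which it passed. Of the 80 probe sets called in control mice, 32 are called higher and 22 lower in noise-exposed mice too.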

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

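The tests of single arrays, of varying amounts of marrow, of neutrophil loss, of probe variants and of the Cdh23 neighbourhood were chosen after the results were seen. The marrow covariate was added after seeing the data, and its test, like those of brighter genes and of other groupings of the arrays, was set before its own result was seen.

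The noise effects of 9 gene lists differed between strains in limma's camera at its preset correlation, always with the smaller or more negative effect in B6.CAST. The mean difference was -2.60 for neutrophil markers, -1.05 for erythroid markers, -0.65 for bone markers, -0.64 for lymphocyte markers, -0.78 for immediate early genes, -0.41 for cytokine and chemokine genes, -0.28 for macrophage markers, -0.27 for spiral ganglion neuron markers and -0.24 for heat shock genes. Without the first control array of B6.CAST the differences were -1.77 for neutrophil, -0.38 for erythroid and -0.16 for bone markers, and without its second noise array that of cytokine and chemokine genes was -0.13. Lymphocyte markers were at -0.39 without the first noise array of 129X1/SvJ, macrophage markers at -0.16 and spiral ganglion neuron markers at -0.17 without its control arrays 1 and 2 in turn, and heat shock genes at -0.13 without its control 3. Of 10 fits that each left out an array, the call was lost in 6 for spiral ganglion neuron, 5 for bone, 3 for lymphocyte, 3 for macrophage and 2 for erythroid markers, 1 for cytokine and chemokine genes and 0 for the other lists. With an estimated correlation, and in fry, 0 of them passed after adjustment. In the control probe sets, which no comparison uses, the 3′ probe set of Actb had a signal of 18313 on the first noise array of 129X1/SvJ, above the highest control array at 7648. The 18S probe set on that array was at 409.7, against 1380 to 6654 on the others.

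The noise effects on immediate early genes had a mean difference of -0.78 ± 0.41 (B6.CAST minus 129X1/SvJ, SE over 10 arrays), with 0 of 24 members called in limma and adjusted p = 0.40 with an estimated correlation. The first noise array of 129X1/SvJ could account for part of this: without it the difference was -0.48 ± 0.16. That is still below 0 by more than its error, and beyond -0.39, the midpoint to 0, by less than its error. More marrow or blood cells on the noise arrays of 129X1/SvJ also remain open, since with the marrow covariate the difference was -0.43 ± 0.50. Among the 12 brighter members it was -0.68 ± 0.30, below 0 by more than its error. It lay beyond -0.39 by less than its error, so an effect of dim probe sets was not excluded either. A weaker response in B6.CAST, as the design would allow, stays open as well, and the arrays are too few to decide.

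Neutrophil markers were lowest on both noise arrays of B6.CAST, at -1.49 and -1.54, just outside the range of -1.18 to 1.16 over all control arrays. Varying amounts of bone marrow in the dissected tissue may explain this, since neutrophil markers tended to vary with erythroid and bone markers within groups. Only Pearson's r with erythroid markers passed after adjustment. After centring on group means over 10 arrays, Pearson's r with neutrophil markers was 0.966 for erythroid and 0.856 for bone markers (exact permutation within groups, two-sided p = 0.014 and 0.069, adjusted over 3 relations 0.042 and 0.069), Spearman's rho was 0.891 for both (p = 0.028 and 0.049, both adjusted to 0.056), and r was 0.954 and 0.824 without the arrays farthest from the median. For lymphocyte markers r was 0.739 (p = 0.035, adjusted 0.052), rho was 0.733 (p = 0.056, adjusted 0.056) and r was 0.597 without those arrays. A loss of neutrophils with noise in B6.CAST was not excluded, since the higher of its noise arrays, at -1.49, lies below every control array, while erythroid markers differed by -0.76 too; S100a8 (named after its values were seen), the brightest of the 13 neutrophil markers, none of which another list holds, had signals of 560.1 and 719.1 on those arrays and 846.5 to 5520 on control arrays.

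Many strain differences in control mice may come from a sequence variant under the probes of a single probe set. For the 22 called probe sets whose gene had another tested probe set, the other showed a median of 0.148 of the called change (quartiles 0.044 and 0.433), while for the 14 such probe sets called for noise in 129X1/SvJ it showed 0.763 (quartiles 0.506 and 1.02), and for the 32 called between strains in noise-exposed mice, where the case is weaker, 0.258 (quartiles -0.015 and 0.682). The 14 count Gadd45b, Socs3 and Cxcl1 with both of their probe sets, each the other of its pair. Some genes among the 32 are counted likewise, and none among the 22, so the medians are not from like sets. Some strain calls may not be of this kind: the other probe set of Atp7a showed 0.757 and that of Iigp1 0.721 of the called change (both named after their values were seen). Genes carried along with the Cdh23 segment were not shown to be the source: 0 of 23 tested neighbours were called, which allows up to 14.8% (exact 95% limit) against 0.941% of other genes. True differences between strains stay open as well.

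Chance was tested by regrouping arrays. For the mean noise effect, 1 of 60 groupings within strains, the real one, gave as many as 40 calls, and the highest other gave 6. That share is under 0.05, which makes chance unlikely but does not exclude it. For noise in 129X1/SvJ the real grouping gave 44 calls and the highest of the others 0, and 10 groupings are too few for a share under 0.05.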

How the results depend on the processing

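The alternatives that use a covariate, leave out both arrays of high Gapdh ratio, cross the numbers or share them across strains were chosen after seeing the data. No detection flags were used, so signal over background limits dim genes in an unknown way. The 101 calls of named genes kept their direction in all 2473 values, of which 1992 stayed past the threshold. These genes were chosen for their calls on the same arrays, most of which each alternative reuses. A kept direction was thus largely fixed in advance and is not independent support. The 44 called lists gave 1121 values, of which 950 stayed past it and 6 changed sign. The cause was not tested, except that a looser threshold gives more calls by construction.

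For noise in 129X1/SvJ (44 calls) array weights gave 71, a threshold of 0.10 68, leaving out both arrays with the other strain spelling 17, no arrays of high Gapdh ratio 22, and leaving out each array 22 to 46. For noise in B6.CAST (4) the count was 2 with a pseudocount of 1 and of 64, 1 with no filter, 0 without the variance trend, 7 with array weights, 0 with its arrays alone, 1 without the arrays of the other spelling, 0 without arrays of high Gapdh ratio, 0 with the marrow covariate, 1 with the Gapdh covariate, and 0 to 5 with each array left out. The mean effect (40) gave 22 without the arrays of the other spelling, 10 without arrays of high Gapdh ratio and 18 to 47 with each array left out. The difference gave 0 under every alternative run.

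The strain difference in control mice (80) gave 139 with array weights, 154 with the compared arrays alone, 37 without the arrays of the other spelling, 131 at 0.10, 36 without arrays of high Gapdh ratio, 35 with the Gapdh covariate and 23 to 132 with each array left out. In noise-exposed mice (126) the same order gave 192, 53, 71, 201, 26 and 100, with 17 for the marrow covariate and 26 to 122 with each array left out. A group left with 1 array is assumed to vary like the others.

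Replicate numbers gave no sign of pairing: same-numbered control and noise arrays had correlations of deviations of -0.15, -0.18 and -0.39 in 129X1/SvJ and -0.17 in B6.CAST. Deviations from a group mean sum to 0, so this check cannot show that the arrays were unpaired. In B6.CAST all pairs give the same value up to its sign. With the number within strain as a block, counts were 25 for 129X1/SvJ, 2 for B6.CAST, 19 for the mean and 0 for the difference. Strain differences cannot be estimated with that block, and a block shared across strains gave 34 in control and 44 in noise-exposed mice. With crossed numbers in B6.CAST, counts were 4, 24 and 0.

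Lists past the threshold numbered 7, 8, 5, 9, 6 and 9 in the order of the comparisons, and with an estimated correlation 0, 0, 2, 0, 0 and 0. Leaving out each array gave 5 to 9 for B6.CAST, 4 to 8 for the mean and 4 to 10 for the difference. With the marrow covariate, B6.CAST had 4 and the difference 3. Both counts leave out the neutrophil and erythroid lists, which form the covariate and were among the 8 and 9. The mean had 3 without the arrays of the other spelling, and control mice 3 with all probe sets of a gene averaged. With the marrow covariate, signs changed for noise in B6.CAST in Hba-a1 (0.011), bone (0.10) and lymphocyte markers (0.083), and for the difference in bone (0.18) and lymphocyte markers (0.0051). With each array left out, the B6.CAST effect ran from -2.32 to 0.090 for Ibsp and -0.95 to 0.017 for bone markers, and stria vascularis markers in noise-exposed mice from -0.094 to 0.53. The strain difference of Gem there, which did not pass, ran from -0.71 to 0.31, and was 0.026 without the arrays of the other spelling. Over all alternatives, the strain difference in noise-exposed mice ran from -0.60 to -0.13 for Ier3 and from -1.52 to -0.22 for Ccl2. With array medians set equal, the median of all probe sets was -0.11 for noise in 129X1/SvJ and 0.16 for the difference.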

Other observations

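The gene list tests were planned, and the unnamed probe sets and the count of shared directions were chosen after the results were seen.

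In the mean noise effect, camera gave no call for markers of hair cells (5 tested of 22, median 0.02 and mean -0.16), supporting cells (8 tested, median -0.10), stria vascularis (8, -0.03), spiral ligament fibrocytes (7, -0.15), spiral ganglion neurons (15, 0.11), Schwann cells (7, median -0.0052), endothelium (11, 0.03) and skeletal muscle (10, -0.14). Antioxidant and metallothionein genes (25 tested, median 0.07), apoptosis and survival genes (23, 0.05), circadian clock genes (14, 0.06), heat shock genes (20, 0.07) and genes near Cdh23 (23, -0.08) gave no call either. Antioxidant and metallothionein genes passed fry (adjusted p = 0.030), with 16 of 25 higher, and 3 higher and 1 lower when adjusted over the list alone. Camera also gave no call for neutrophil (13, -0.41), erythroid (9, -0.29), lymphocyte (8, -0.02) and bone markers (8, -0.16). Over these 17 lists the adjusted p from limma's camera ranged from 0.064 to 0.73, which does not show that the groups were level.

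A probe set without a gene name here had the largest change with noise of any probe set called in 129X1/SvJ. It rose by 5.03 ± 0.42 in 129X1/SvJ and by 3.81 ± 0.51 in B6.CAST (adjusted p = 0.00027 and 0.037 in limma). A further unnamed probe set rose by 1.03 ± 0.12 in 129X1/SvJ.

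Of the 40 probe sets that rose with noise in 129X1/SvJ, 39 were also higher with noise in B6.CAST, and all 4 that fell were lower there. The arrays of the strains are separate, and genes are not independent replicates.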
